A study of Mus musculus with 6 samples.

How the data were processed

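ATAC-seq libraries were made from mouse embryonic fibroblasts of 3 groups with 2 libraries each, from 50k cells per library with an Omni-ATAC protocol and 12 cycles of amplification, per the labels' protocols. The labels do not say whether the 2 libraries of a group came from separate cultures. Per the submitters' processing notes, BWA, MACS2 and DESeq2 were used with GRCm38.p6, without versions or roles. Per the file headers, the authors ran HOMER's annotatePeaks on a set of consensus peaks with a GRCm38.p6 sequence and the GENCODE vM23 annotation. How peaks were called and joined, at which threshold, on single or pooled libraries, and with which filters is not given in the sources used here.

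The table used here lists 323483 intervals with chromosome, start and end, 1-based. Its peak score is 0 throughout and its annotation columns hold no values, so both were not used. No column names a library or a group. Every planned comparison between groups (tests per interval, peak presence per group, gene list changes, leaving out libraries) was therefore not run, and the interval positions alone were described. Depth per library was not analysed here. Because intervals come from a joined set, a wide interval can be several peaks of different libraries merged, and an interval can stem from a single group.

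Gene positions came from the RefSeq gene table of the same assembly, GRCm38.p6, with 21883 protein-coding genes used. This table has no strand, so start sites are unknown, and the planned start-site distances were replaced by the distance to either gene end. A gene whose annotated end lies far from the start site used in these cells can therefore lack a gene-end interval while its promoter is accessible. Motif counts were not run, because no genome sequence was used here. Intervals were classed by their midpoint, as at a gene end (within 1 kb), over a gene body, or outside genes. Those outside were split at up to 10 kb, 10 to 100 kb or beyond. Per gene, a gene-end interval was instead one overlapping the 1 kb on either side of an end by at least 1 bp. The classes were compared with 1000 circular shifts of all intervals along their chromosomes, two-sided.

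Each interval was assigned to its nearest protein-coding gene at any distance, and an interval over several genes was counted for each of them. Genes that overlap or lie close can therefore share intervals, which random lists drawn gene by gene do not mirror. The room around a gene (its territory) runs from the midpoint to the preceding gene to the midpoint to the following gene. A list's median number of intervals, and its share of genes with a gene-end interval, were set against 10000 random lists of the same size drawn from 20 bins of territory (seed 1, two-sided), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. These p-values compare genes within a single interval set and carry no replicate error. The 19 lists had 300 distinct symbols, of which 298 matched the gene table, and Cyr61 and Ctgf are older symbols of listed genes. The lists, the initial set of alternative settings and the rule for named genes were fixed before the data were examined. Widths at gene ends were compared between 6 pairs of lists with permutation tests (100000 resamples) and Fisher's exact test. The circular shifts, the comparisons of chromosomes, the gene-end measures of the lists, these pairs, the 26 gene families defined by symbol, the tests of the X chromosome by thinning and over genes with an accessible end, of stretches without intervals and of the cover of Myf6 were chosen after the data were seen.

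Named genes followed a fixed rule: per list the 4 genes with the most intervals and up to 4 with none, the 20 genes with the most intervals, and all intervals within 10 kb of Myf6, Myod1, Myog, Myf5, Pax7 and Pax3. Of the genes taken by this rule, 2 are not reported here. Up to 4 genes per list with no interval at an end were added after the data were seen. The random-list test was tested on simulated data: of 40 lists of 20 genes drawn from 21883 genes at random, 7.5% were called at an unadjusted p of 0.05, and with intervals raised 2-fold and 3-fold 80% and 85% were called. Simulated counts were drawn anew within the same bins of territory, with fewer random lists than in the main test. Bias within a bin, or from listed genes that share intervals, could therefore not show. The shares called do not give the power of the adjusted test, of lists with fewer genes or of smaller rises. Alternatives covered the assignment distance, means for medians, unmatched lists, matching on gene length, a background without olfactory, vomeronasal and predicted genes, minimum widths of 300 and 600 bp, other gene-end distances, genes with an end interval only for the widths, all RefSeq genes, and weighting by length. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.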

Results

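Open chromatin was profiled by ATAC-seq, in which a transposase inserts adapters into accessible DNA, in mouse embryonic fibroblasts carrying a tetracycline-controlled Myf6 transgene together with the reverse transactivator M2-rtTA. Myf6, also called Mrf4, is a basic helix-loop-helix regulator of skeletal muscle. The cells were heterozygous for both alleles and were kept for 24 h in medium with 10 ng/mL bFGF. Of the 3 groups, each with 2 libraries, the medium group received no further addition and the Myf6 group received doxycycline at 2 µg/mL to switch the transgene on. The third group, Myf6 with F/R/C, received doxycycline together with forskolin at 5 µM, RepSox at 5 µM and CHIR99021 at 3 µM. Forskolin activates adenylate cyclase, RepSox inhibits the TGF-beta type I receptor and CHIR99021 inhibits glycogen synthase kinase 3.

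The design asks which sites open or close when Myf6 is induced and what the 3 compounds add. The data analysed here were the consensus set of 323483 accessible intervals, joined over the experiment, with positions on the mouse genome GRCm38.p6 and no value for any library or group. Differences between the 3 groups were therefore not analysed here, the read depth behind each interval is unknown, and no value below has a replicate error. An interval says that a peak was called there in the experiment, without saying in which group. What follows describes where the accessible sites of the experiment lay, with the induced gene first.

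The Myf6 gene, on chromosome 10 from 107492848 to 107494723 (gene ID 17878), was covered by intervals over 74.5% of its length. A pair of intervals lay inside it, from 107493204 to 107494093 (890 bp) and from 107494199 to 107494705 (507 bp), and neither reached the first or last base of the gene. The median protein-coding gene of 1 to 4 kb had 9.51% of its length covered, and 103 of the 2636 genes of that size (3.91%) had cover as high as Myf6. Another 8 intervals lay within 10 kb of Myf6, of which 3 overlapped its neighbour Myf5 and 5 lay on the other side, between 107499818 and 107503824, with the widest at 107502109 to 107502765 (657 bp). Reads from the transgene and from the endogenous gene cannot be separated in these intervals, which limits what the cover of Myf6 shows.

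Among the other myogenic regulators of the same protein family, Myf5 (chromosome 10, 107482908 to 107486927, gene ID 17877) had 26.6% of its length in 3 intervals, of which that at 107486844 to 107487035 (192 bp) spanned the gene end nearer to Myf6. Myod1, which can convert fibroblasts into muscle cells, lay on chromosome 7 from 46376474 to 46379092 (gene ID 17927) and had 4 intervals within 10 kb. Those over Myod1 were at 46377009 to 46377297 and 46378190 to 46378501, those beyond it were at 46379102 to 46379316 and 46380501 to 46380915, and the widest measured 415 bp. Intervals covered 23.0% of Myod1. Myogenin (Myog, chromosome 1, 134290004 to 134292548, gene ID 17928), which acts in terminal differentiation, had 11 intervals within 10 kb and 31.8% of its length covered. A Myog interval of 583 bp, from 134289575 to 134290157, spanned the lower gene end, and an interval of 1147 bp, from 134298626 to 134299772, lay 6078 bp beyond the other end, inside Ppfia4.

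The paired-box factors of muscle progenitors had longer genes and more intervals. Pax7 (chromosome 4, 139737059 to 139833530, gene ID 18509), a marker of satellite cells, had 18 intervals within 10 kb, 15 of them over the gene, covering 7.30% of it. The Pax7 intervals gathered toward its upper end, where intervals of 753 bp (139832535 to 139833287), 237 bp (139833372 to 139833608) and 465 bp (139833898 to 139834362) followed each other. Pax3 (chromosome 1, 78101267 to 78197136, gene ID 18505) had 23 intervals within 10 kb, 17 of them over the gene, covering 6.79% of it. An interval of 1084 bp (78196371 to 78197454) spanned the upper end of Pax3, and the widest near it, 1638 bp (78202997 to 78204634), lay 5861 bp beyond that end.

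**Figure D1:**
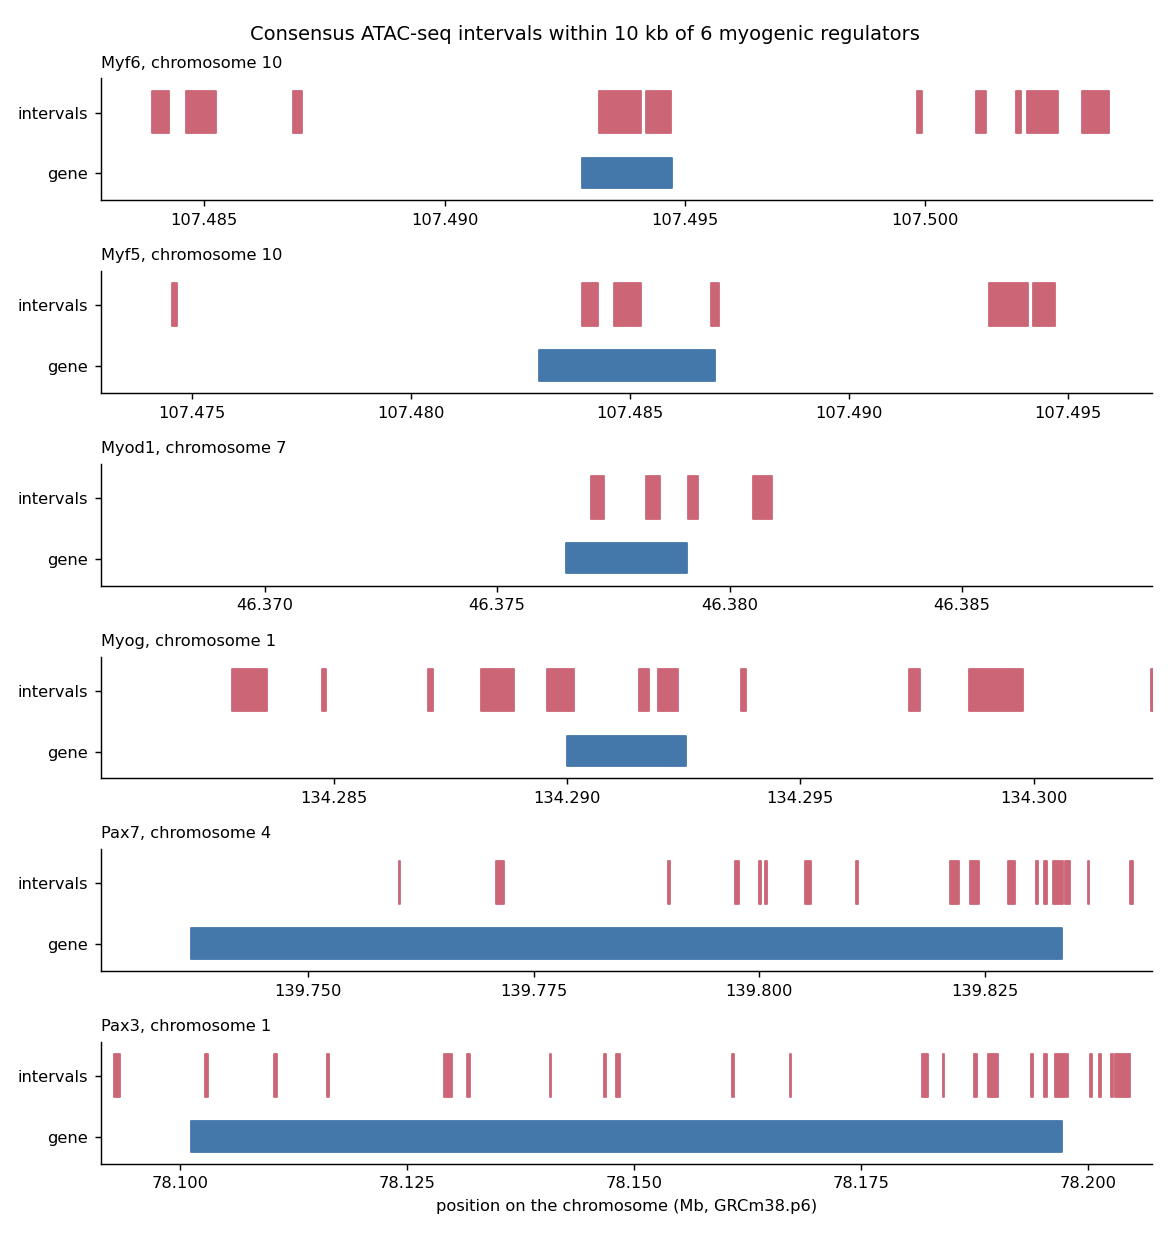
Consensus intervals (red) and gene bodies (blue) within 10 kb of Myf6, Myf5, Myod1, Myog, Pax7 and Pax3, drawn to scale against the position on the chromosome in Mb (GRCm38.p6). The intervals inside Myf6 fill 74.5% of the gene, against 23.0% for Myod1, and neither reaches a gene end.

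Muscle genes as groups held somewhat more intervals than random gene lists, without passing the test. Most of the 19 lists lay above random lists too, epithelial and housekeeping genes among them, so this was not particular to muscle. Each interval was assigned to its nearest protein-coding gene, and each list was compared with 10000 random lists whose genes had as much room around them (two-sided, Benjamini-Hochberg adjusted over 19 lists). The 15 myogenic regulators had a median of 23 intervals per gene against 13 for random lists (adjusted p = 0.236). Mef2c (99 intervals), a MADS-box partner of the myogenic factors, Tcf12 (99), the E-protein HEB, Eya1 (72) and Myocd (63) held the most. Counts of single genes, here and below, are not adjusted for the room around the gene. Per 100 kb of room, Mef2c, Tcf12, Eya1 and Myocd held 7.65, 27.0, 12.1 and 20.3. The median over all protein-coding genes was 16.8. Mef2a, with 56 intervals, had none within 1 kb of either gene end, and the other 14 regulators had at least 1 there. The 20 muscle progenitor and satellite cell markers had a median of 18.5 against 13.5 (adjusted p = 0.288), led by the Notch target Hes1 (79), Pax3 (72), Dmrt2 (55) and Cd82 (54), and all 20 had an interval at a gene end. Within 10 kb of the gene, Hes1, Pax3, Dmrt2 and Cd82 held 13, 23, 3 and 26. The 36 genes of myocyte differentiation and the sarcomere had a median of 7 against 5 (adjusted p = 0.236). In that group dystrophin (Dmd, 55), the ryanodine receptor Ryr1 (31), nebulin (Neb, 30) and titin (Ttn, 27) held the most intervals, and Myl1, Myh2, Myh4 and Myh8 had none at a gene end. Myh4 and Myh8, myosin heavy chains of fast and developing fibres, held 1 interval each in 37.6 and 49.1 kb of surrounding sequence.

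Genes of the fibroblast and its matrix all had accessible gene ends. All 28 had an interval within 1 kb of an end, against 75% in random lists (adjusted p = 0.0228), and in all 28 the widest of these measured at least 600 bp. Their median of 26.5 intervals per gene against 16 did not pass the test (adjusted p = 0.0950). Zeb2 (243 intervals), a repressor of epithelial genes, Fn1 (106), which encodes fibronectin, Zeb1 (106) and the collagen gene Col5a1 (96) held the most. The gene-end call ended when olfactory, vomeronasal and predicted genes were left out of the background (adjusted p = 0.312) and with a distance of 5 kb (adjusted p = 0.150).

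Of the signalling groups that the 3 compounds act on, the TGF-beta response genes stood above random lists. Their 21 genes had a median of 29 intervals against 15 (adjusted p = 0.0304), and 20 had an interval at a gene end. Ltbp1 (138 intervals), which encodes a binding protein of latent TGF-beta, the ligand gene Tgfb2 (78), the transducer Smad3 (67) and the cell cycle inhibitor Cdkn2b (62) held the most, and Tgfb2 was the gene with no interval at an end. The 20 Wnt and beta-catenin response genes had a median of 32 against 18.5 (adjusted p = 0.102), with Tcf7l2 (125), Ctnnb1 (69), Tcf7l1 (58) and Lef1 (51) in front. Axin2, a feedback inhibitor of Wnt signalling, held 33 intervals and none at an annotated end. The 20 cAMP response genes had a median of 32 against 22 (adjusted p = 0.236), and the phosphodiesterase genes Pde4d (287), Pde10a (150) and Pde4b (130) and the coactivator gene Ppargc1a (142) held the most. Pde4d had none at an end. The 12 AP-1 genes, which encode transcription factors of the Fos, Jun and related families, had a median of 10 against 5.5 (adjusted p = 0.135), and all 12 had an end interval of at least 600 bp, with Jun (62), Fos (33), Fosl2 (32) and Atf3 (23) in front. The TGF-beta call ended when only intervals within 10 kb of a gene counted (adjusted p = 0.0823) and with the smaller background (adjusted p = 0.0627).

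The Hox genes of limb and trunk, which encode positional identity and were listed with other limb regulators, had the lowest adjusted p of the 19 lists. These 15 genes had a median of 7 intervals against 3 (adjusted p = 0.0038), and 14 had an interval at an end. Neighbouring genes of a cluster can share intervals, which the random lists do not mirror. Tbx4 (35), Pitx1 (25), Tbx5 (24) and Hoxa13 (16) held the most, and Tbx5 was the gene without an end interval. The call ended when random lists were matched on gene length (adjusted p = 0.184) or not matched (adjusted p = 1.0), or when means replaced medians (adjusted p = 0.124).

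Markers of other cell types did not pass the test in either direction. The 10 smooth muscle genes had a median of 18 intervals against 8.5 (adjusted p = 0.102), with Myocd (63), Itga8 (52), Synpo2 (49) and Smtn (23) in front, and the 12 cartilage and bone genes had 19 against 11.5 (adjusted p = 0.236), with Sox5 (194), Sox9 (124), Runx2 (108) and Sox6 (85). The 10 adipocyte genes had a median of 14 against 7.5 (adjusted p = 0.236), led by Zfp423 (95) and the adipogenic regulators Pparg (43) and Cebpa (18), with Lep at 23, and Cidec had no interval at an end. Endothelial genes had a median of 40 against 27.5 (adjusted p = 0.236), with Cdh5 (131), Erg (55), Kdr (46) and Emcn (45) in front, and Emcn, Vwf and Pecam1 had none at an end. Among 10 macrophage and blood cell genes the median was 6.5 against 7 (adjusted p = 0.955), and Ptprc (102 intervals), Fcgr1, Tyrobp and Adgre1 had none at an end. Adgre1, which encodes the macrophage antigen F4/80, had no interval at all in 152.2 kb, while Itgam (15), Csf1r (14) and Spi1 (9) had some. Neuronal genes had 16 against 20 (adjusted p = 0.653), led by Myt1l (67), Map2 (52), Stmn2 (47) and Rbfox3 (42), with no end interval at Dcx and Neurod4. Epithelial genes had 9.5 against 6.5 (adjusted p = 0.248), led by Grhl2 (40), Cdh1 (23), Epcam (20) and Esrp1 (14), with no end interval at Krt5. Pluripotency genes had 8 against 11 (adjusted p = 0.586), led by Klf4 (134), Sox2 (93), Esrrb (34) and Tfcp2l1 (19), while Nanog, Pou5f1 and Zfp42 had no interval at an end. Several of the highest counts in these lists came from far around the gene. Within 10 kb, Sox5 held 150, Klf4 8, Cdh5 21, Sox9 8, Runx2 88, Ptprc 10, Zfp423 84 and Sox2 6.

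Genes used in most cells were also compared. The 14 cell cycle genes had a median of 9.5 intervals against 6 (adjusted p = 0.236), all 14 had an end interval of at least 600 bp, and Mki67 (96), Rb1 (28), Cdk1 (27) and Cdkn2a (22) held the most. Within 10 kb, Mki67, Rb1, Cdk1 and Cdkn2a held 7, 26, 13 and 14. The 15 housekeeping genes had a median of 5 against 3 (adjusted p = 0.253), with examples in Ywhaz (66), Hprt (16) and Actb (11).

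Sarcomere genes had narrower accessible gene ends than fibroblast or progenitor genes. The widest interval at an end of each gene had a median of 745 bp over the 36 sarcomere genes and 1404 bp over the 28 fibroblast genes (two-sided permutation test of medians, 100000 resamples, p = 4e-05, adjusted p = 2.4e-04 over 6 pairs of lists), with 0 for the genes without such an interval, 4 of the sarcomere and none of the fibroblast genes. For the 20 progenitor markers the median was 1175 bp, above the sarcomere genes (permutation p = 0.00382, adjusted p = 0.0115) and not distinguishable from the fibroblast genes (permutation p = 0.135, adjusted p = 0.203). Sarcomere genes did not differ past the threshold from the epithelial genes (873.5 bp, adjusted permutation p = 0.485), the neuronal genes (931 bp, 0.348) or the macrophage and blood cell genes (297 bp, 0.128, with 4 of 10 at 0). Over genes with an end interval only, sarcomere genes had a median of 808 bp, still below fibroblast (adjusted permutation p = 0.00252) and progenitor genes (0.0218), and the macrophage and blood cell genes had 840.5 bp (0.848). All protein-coding genes with an end interval had a median of 1243 bp (quartiles 883 and 1610 bp). The fibroblast and progenitor medians lay between these quartiles, and the sarcomere median lay below them. The share of genes with any end interval differed in none of the 6 pairs (Fisher's exact test, lowest adjusted p = 0.329). Width is the extent of the joined peaks and not a signal level. The pairs were not matched on room or gene length, and they were chosen after the data were seen.

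**Figure D2:**
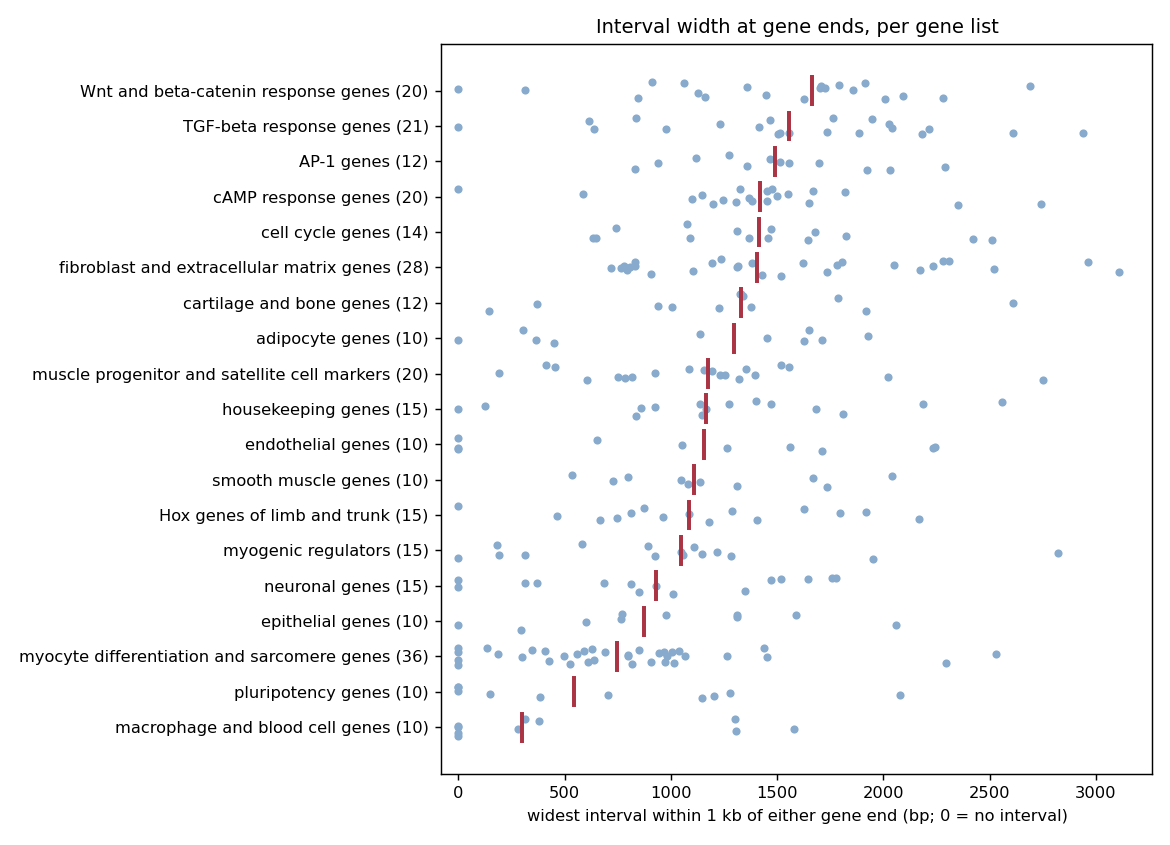
Widest interval within 1 kb of either gene end, in bp, for each gene (points, spread vertically at random) of the 19 lists, with the number of genes in brackets, 0 for genes without such an interval, and red bars for medians. Sarcomere genes have a median of 745 bp, fibroblast genes 1404 bp and macrophage and blood cell genes 297 bp.

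The genes with the most assigned intervals were long genes or genes in wide gene-poor surroundings. Auts2 (335 intervals), Adgrl2 (317), Rbms3 (305), Tenm4 (298), Tenm3 (296), Lpp (287), Pde4d (287), Myc (264), Zfp608 (259) and Adgrl3 (253) were followed by Cdh11 (247), Zeb2 (243), Pard3 (240), Flrt2 (233), Macrod2 (231), Foxp1 (228), Efnb2 (227), Efna5 (224), Mctp2 (217) and Zmiz1 (217). Myc, the proto-oncogene on chromosome 15 from 61985341 to 61990361, is only 5.02 kb long and gathered its intervals from 1430 kb. Per 100 kb, these genes ranged from 7.58 (Adgrl3) to 30.9 (Zmiz1), against a median of 16.8 over all protein-coding genes. By density, among the 6078 genes with at least 100 kb around them, the perlecan gene Hspg2 came first with 53.4 intervals per 100 kb. Genes of adhesion, matrix and the actin cytoskeleton were among the next 19, including Afap1 (46.1), Cd44 (45.5), Col5a1 (41.2), Actn1 (41.1), Myh9 (40.9) and Lamb1 (40.5), as was the chromatin protein gene Hmga2 (45.5). These density examples were picked after their values were seen, and no enrichment was tested.

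By the share of sequence covered, the first window of 100 kb lay over Septin9 on chromosome 11 (117300001 to 117400000), where 58 intervals covered 28.5% of the sequence, against a median of 4.60% over 26331 windows. The next were the window of Capzb and Slc66a1 on chromosome 4 (139200001 to 139300000, 27.8%) and that of the HoxA cluster on chromosome 6 (52200001 to 52300000, 25.7%, 52 intervals), which holds Hoxa3 to Hoxa13. No interval was found in 3565 windows.

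Gene ends held more intervals, and wider ones, than chance placement. Of all intervals, 22359 (6.91%, 95% Wilson interval 6.83 to 7.00%) had their midpoint within 1 kb of either end of a protein-coding gene. The shifted share was 3.08% ± 0.063 (SD over 1000 circular shifts of the intervals), a ratio of 2.24. Another 48.5% had their midpoint over a gene body away from its ends (38.6% after shifting). Intervals with their midpoint more than 100 kb from any protein-coding gene made up 14.4% against 27.9%. Each of these differences had a circular permutation p = 0.002, the smallest that 1000 shifts can give. Gene-end intervals had a median width of 805 bp, against 323 bp over gene bodies and 303 bp beyond 100 kb. In the widest decile of intervals 30.2% lay at a gene end, 9.63 ± 0.42 times the shifted share, and in the narrowest decile (96 to 131 bp) the ratio was 1.27 ± 0.046. Of the 21883 protein-coding genes, 16337 (74.7%) had an overlapping interval at an end and 6933 (31.7%) at both, and the median gene was assigned 6 intervals. Shifted intervals also fall on unassembled or poorly mappable sequence, which was not corrected for.

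**Figure D3:**
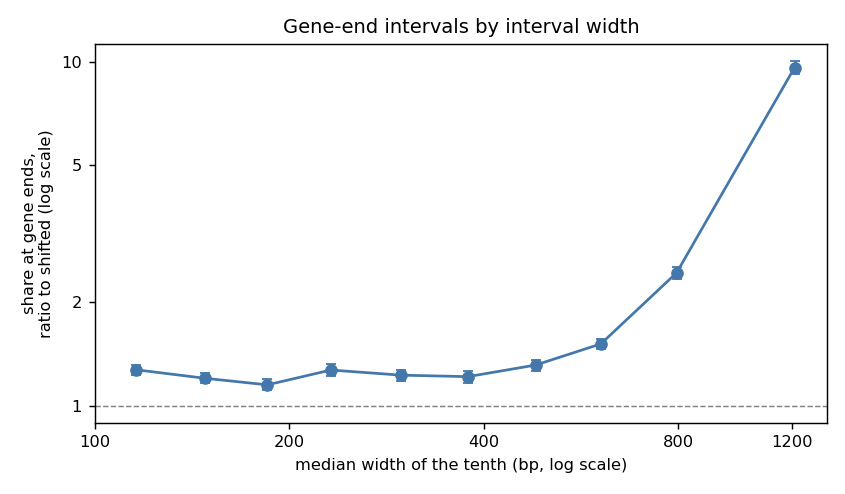
Ratio of the observed to the circularly shifted share of intervals with their midpoint within 1 kb of a gene end (log scale) against the median width of each decile of interval width (bp, log scale), with bars for the SD over shifts and a dashed line at 1. The ratio stays between 1.15 and 1.51 up to the decile with a median of 607 bp and reaches 9.63 in the widest.

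Accessible sites were sparse on the X chromosome. The 19 autosomes held 130.9 ± 12.5 intervals per Mb (mean and SD over chromosomes), from 109.7 on chromosome 14 to 160.2 on chromosome 11, and X held 49.5. Genes on X shared this: 803 X genes outside the olfactory, vomeronasal and predicted ones had a median of 5 intervals, against 12 (central 95% 11 to 13) in 1000 random lists of autosomal genes with as much room (random-list permutation p = 0.002, the smallest they can give). At least 1 gene end was accessible in 65.1% of these X genes, against 85.1% in the autosomal lists. The dystrophin gene Dmd, on X from 82814664 to 85205050, held 1.78 intervals per 100 kb. The Y chromosome held 27 intervals, whose nearest genes were Uty (11), Eif2s3y (5), Zfy2 (4), Kdm5d (4), Ddx3y (2) and Uba1y (1). All 27 lay between 809109 and 2341345, in a span of 90.7 Mb. Those assigned to Zfy2 lay 162422 to 170713 bp from it, and the others at most 24364 bp from their gene. To how much of Y reads can be mapped was not examined, which limits what its density shows. Among the 19 autosomes, interval density rose with gene density (Pearson r = 0.52, permutation p = 0.0230, and 0.66 without the 2 chromosomes farthest from the median gene density; Spearman rho = 0.46, permutation p = 0.0486). Chromosomes are not independent replicates, and these were the only correlations computed.

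**Figure D4:**
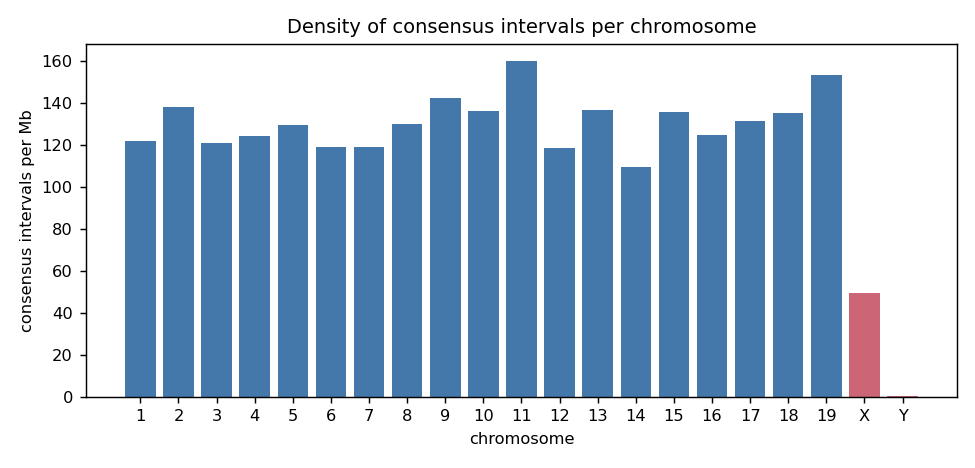
Consensus intervals per Mb (bars, from 0) on chromosomes 1 to 19 (blue) and on X and Y (red). Autosomes range from 109.7 to 160.2 intervals per Mb, X has 49.5 and Y 0.298. The values are not corrected for sequence to which reads cannot be mapped.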

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

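Intervals outside the assembled chromosomes drew attention because no comparison of the results uses them. There were 86 such intervals on 12 unplaced scaffolds, above the 3 that a count of 0 would allow. Of these, 55 lay on a single scaffold, where they covered 33.8% of the 98.1 kb from the first to the last of them. The most covered 100-kb window of the chromosomes had 28.5%. These shares are not alike, since the scaffold span was trimmed to its intervals, which raises its share, and the windows were fixed. A further scaffold held 10 intervals, which covered 2.69% of a span of 156.8 kb measured in the same way. The mitochondrial genome held 0 intervals.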

How the results depend on the processing

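No paired analysis was possible because no column of the table names a library, so neither a fit with the replicate number as a block nor any fit per library could be made. For the same reason the planned count tests, normalisations, peak filters, left-out libraries and gene list tests between groups were not run, nor were the motif and start-site alternatives, and the unknown depth limits every statement. Planned settings were the 10 and 100 kb assignments, means, unmatched lists, the 300 bp minimum for classes and intervals per gene, chromosomes 1 to 19 and X, and weighting by length. For the random lists the plan named matching on gene spacing or on gene length. Room around the gene was taken for the main test and gene length as an alternative. The remaining settings, the circular shifts, and every result on the gene ends of lists, families and list pairs, were added after the data were seen. The excess at gene ends and over gene bodies and the deficit beyond 100 kb held under all 5 alternatives. The share at gene ends ran from 6.91% (3.085% after shifting) on chromosomes 1 to 19 and X to 19.1% (12.7% after shifting) with a distance of 5 kb. The wider distance thus raised the shifted share as well. Direction and side of the threshold were also kept in 104 of 133 values for intervals per gene of the lists, 93 of 114 for gene ends, 32 of 52 for families and 21 of 24 for list pairs. Values past or short of the threshold otherwise were as follows, each bracket giving the value (median or mean intervals per gene, percent of genes or bp) and then the adjusted p of the random lists, and their cause was not tested except where said.

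Lists past the threshold for intervals per gene numbered 2. With intervals within 10 kb the number was 1, TGF-beta genes fell short (18, 0.0823) and neuronal genes turned above random (10, 1.0). With means, Hox genes fell short (11.1, 0.124), fibroblast genes passed (46.8, 0.0019), and macrophage (16.2, 0.812) and pluripotency genes (31.7, 0.504) turned above. With unmatched lists the number was 7. Hox genes fell short (7, 1.0), and the Wnt (32, 0.00127), cAMP (32, 0.00127), endothelial (40, 0.0038), fibroblast (26.5, 0.0019), progenitor (18.5, 0.0206) and myogenic lists (23, 0.0206) passed. Neuronal (16, 0.0958) and pluripotency genes (8, 0.929) turned above and housekeeping genes (5, 0.929) below. With intervals of at least 300 bp the number was 5, as AP-1 (7, 0.0312), Wnt (21, 0.0143) and fibroblast genes (17, 0.0127) passed, and neuronal genes turned above (11, 1.0). With matching on gene length the number was 6. AP-1 (10, 0.0272), Wnt (32, 0.0019), cAMP (32, 0.0133), fibroblast (26.5, 0.0019) and progenitor genes (18.5, 0.0137) passed, Hox genes fell short (7, 0.184), and neuronal (16, 0.631) and pluripotency genes (8, 0.253) turned above. Without olfactory, vomeronasal and predicted genes in the background the number was 1, since TGF-beta genes fell short (29, 0.0627). Room around the genes and silent genes in the background were each set as a cause of the number of lists before these results. The fall from 7 to 2 on matching and from 2 to 1 with the smaller background met what each needs, the latter by 1 list. Over all settings the adjusted p ranged from 0.00127 to 0.0823 for TGF-beta genes and from 0.0038 to 1.0 for Hox genes.

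Lists past the threshold for gene ends numbered 1, the fibroblast genes, and 0 with the smaller background (100%, 0.312) or a distance of 5 kb (100%, 0.150). At 5 kb endothelial (100%, 0.488), macrophage (90%, 0.914) and pluripotency genes (90%, 0.914) turned above. With intervals over the end base itself the number was 7, as AP-1 (100%, 0.0241), TGF-beta (90.5%, 0.0486), cAMP (90%, 0.0494), cell cycle (92.9%, 0.0494), progenitor (95%, 0.0209) and smooth muscle genes (100%, 0.0486) passed. Myogenic, adipocyte and epithelial genes (60% each, 1.0) turned below and endothelial genes (70%, 1.0) above. With intervals of at least 600 bp the number was 4, as AP-1 (100%, 0.0437), TGF-beta (95.2%, 0.0304) and cell cycle genes (100%, 0.0304) passed, and sarcomere (61.1%), adipocyte (60%) and endothelial genes (70%, 1.0 each) changed side of the random value.

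Families past the threshold numbered 11, and 17 with unmatched lists. There ADAM proteases (14, 0.006), Kruppel-like (28, 0.0026), Sox (17, 0.0281) and forkhead factors (16, 0.00156), integrins (15, 0.0175), potassium channels (14.5, 5.78e-04) and histones (1, 5.78e-04) passed. Hox genes (5, 0.626), ribosomal proteins (4, 0.104), proteasome subunits (6, 1.0), keratins (4, 0.203), troponins (4, 0.603) and, past the threshold, Zic and Irx factors (30, 0.0100) changed side. With the smaller background the number was 9, as phosphodiesterases (34.5, 0.108) and protocadherins (12, 0.319) fell short, and ADAM proteases (14, 0.886), Sox (17, 0.992) and T-box factors (17, 1.0), keratins (4, 1.0) and potassium channels (14.5, 0.992) changed side. Among list pairs, progenitor minus fibroblast widths passed with means (-415 bp, unadjusted permutation p = 0.0317), and sarcomere minus neuronal widths turned positive over the end base (15 bp, permutation p = 1.0). Over genes with an end interval only, sarcomere minus macrophage widths turned negative (-32.5 bp, permutation p = 0.848), since this setting leaves out 4 genes of each list that counted as 0.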

Other observations

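The gene families, the tests of stretches without intervals and of Myf6, and the tests of X by thinning and over genes with an accessible end were chosen after the results were seen, and the test of X genes without olfactory, vomeronasal and predicted genes was set before its result was seen. Few olfactory and vomeronasal receptor genes had an interval at an end. Of 1110 olfactory receptor genes 74 (6.67%) had an interval at an end, and of 355 vomeronasal receptor genes 6 (1.69%), against 72.3% and 73.5% in random lists with as much room (adjusted p = 8.67e-04 for both). Their median number of intervals was 0, against 4 and 7. Beta-defensins (median 0.5 against 4) and cytochrome P450 genes (2 against 9, with 36 of 99 accessible at an end) were also below (adjusted p = 7.43e-04 for both). The longest gap on an autosome, 4.00 Mb on chromosome 7 (19965428 to 23968118), holds 84 vomeronasal receptor genes, and a gap of 3.51 Mb on chromosome 17 (37277330 to 40791335) holds 37 olfactory receptor genes. Closed chromatin cannot be told here from sequence to which reads cannot be mapped or from regions left out in processing, since neither was examined for these families. The Zfp zinc finger genes had fewer intervals (4 against 6) but more often an accessible end (85.6% against 73.8%, adjusted p = 8.67e-04).

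Collagens, semaphorins and plexins were above random lists with as much room, while integrins (15 against 10, adjusted p = 0.156) and ADAM and ADAMTS proteases (14 against 13, adjusted p = 0.872) did not pass. Collagens had a median of 35 intervals against 19 (adjusted p = 0.00173), and semaphorins and plexins, which guide axons and other cells, had 26 against 10 (adjusted p = 7.43e-04), with all 29 accessible at an end. Phosphodiesterases (34.5 against 18, adjusted p = 0.0400) and clustered protocadherins (12 against 5, adjusted p = 0.0487) were above too, but neither with the smaller background (adjusted p = 0.108 and 0.319). The protocadherins had fewer accessible ends (61.4% against 77.2%, adjusted p = 0.0219). Clustered genes, such as these and the Hox genes, can share intervals and ends. The random lists do not mirror this, so their p-values treat such genes as more independent than they are. Hox genes (5 against 2, adjusted p = 7.43e-04, with 39 of 39 accessible at an end) and ribosomal protein genes (4 against 2, adjusted p = 0.0013, with 81 of 83 accessible) were above these lists, and did not pass against lists not matched on room (adjusted p = 0.626 and 0.104). In all, 15 of the 26 families did not pass the test for intervals per gene. Among other kinds of genes, 67.0% of long noncoding RNA genes, 65.9% of tRNA genes and 22.5% of pseudogenes had an interval at an end, against 74.7% of protein-coding genes.

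Long stretches without intervals covered a few genes that most cells use. Of 135 housekeeping, ribosomal and proteasome genes 3 had no interval assigned and none within 1 kb of an end, among them the proteasome genes Psma7 and Psmc5, in stretches of 69.3 kb (chromosome 2, 180025641 to 180094909) and 50.5 kb (chromosome 11, 106252074 to 106302559). The 3 stretches were not gene-poor, since they held 11 protein-coding genes besides these 3, among them Smarcd2 and Ss18l1. That is 4.945 per 100 kb (exact Poisson 95% interval 2.47 to 8.85), against a mean of 0.813. The stretches were found by genes that most cells use, and the Poisson interval treats genes as independent. Gene density therefore cannot tell closed chromatin from a loss in processing. Whole regions left out in processing, by a filter of regions for example, may be the cause, as each flank of 100 kb held at least 20 intervals against a mean of 12.0. Such flanks could also border closed chromatin. The groups of the design offer no biological explanation to test, and 35 stretches of this kind, with 323 genes, include families with few intervals, such as olfactory receptors.

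The cover of Myf6 may come in part from the transgene, whose reads would map to the endogenous gene and stop short of its ends. Of the 2636 protein-coding genes of 1 to 4 kb, 4 (0.152%), Myf6 among them, had cover as high with both end bases free. This count decides nothing, since it was built on the features of Myf6 that raised the question, and accessible endogenous Myf6 and transgene reads cannot be told apart, because the intervals carry no reads and no group. An opening of the endogenous gene on induction stays open and was not tested.

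The low density on X was weighed against silent genes and against an even loss. Olfactory, vomeronasal and predicted genes were argued against as the only cause, since X genes outside them had a median of 5 intervals against 12 (11 to 13). The 523 of these with an accessible end had 8 against 15 (14 to 16) in autosomal genes with an accessible end. This argues against silent genes of other kinds as the only cause, as far as an accessible end marks a gene in use. Whether silent genes add to the low density cannot be told from it. Loss of the same share of intervals from every kind of site was argued against as well, since 65.1% of X genes kept an accessible end, against 51.9% (50.1 to 53.7%) for autosomal genes thinned to 44.6% of their intervals. A loss that spares strong sites, as fewer reads from a single copy of X per cell could give, stays open. The X to autosome ratio was 0.752 for ends with an interval of at least 600 bp and 0.766 for any accessible end. Both are yes-or-no measures, which saturate, so these ratios do not decide it. Gene-end intervals on X had a median of 869 bp, within the autosomal range of 727 to 903 bp. A test set earlier for such a loss compared the X to autosome ratio for accessible ends with that for mean intervals (0.446). It was void for the same reason, and the groups of the design offer no biological explanation to test.

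Measured between midpoints, the narrowest decile of intervals lay within 5 kb of an interval of at least 600 bp in 42.4% of cases, against 27.4% after shifting, a ratio of 1.54 ± 0.027. This was not particular to the narrowest, since the following deciles had ratios of 1.52 to 1.54 up to a median width of 298 bp.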
